A study of Homo sapiens with 2 samples.

How the data were processed

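One pulldown of chromatin was analysed, from SEM cells in which the endogenous MYB gene carries an FKBP12(F36V) tag. SEM is a leukaemia cell line with the t(4;11) translocation, which fuses KMT2A (MLL) to AFF1 (AF4). The FKBP12(F36V) tag is a degron that lets a small molecule remove the tagged protein. The cells analysed here had received the vehicle DMSO, and the library name gives 24 hours. The labels name HA as the pulldown's target, and that the HA epitope is part of the tag on MYB is inferred from this. Per the labels' protocols, chromatin was crosslinked, sonicated, immunoprecipitated and then tagmented with a transposase, a protocol the submitters call TOPmentation. An input library of the same culture condition served the authors as the control for peak calling, and only its effect on the peak list was used here. Nothing in the labels says that the pulldown was repeated or pooled, so every value describes 1 library.

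The deposited file is a peak list. Per the file headers, the authors called peaks with HOMER findPeaks on 14948117 tags, with a fixed peak size of 145 bp and at least 290 bp between peaks. The authors' threshold was a false discovery rate of 0.001, which came to 10 tags per peak. Per the file headers, each peak also had to exceed the input and the surrounding 10000 bp by 4-fold, with a Poisson p-value of 0.0001 for each. The candidates numbered 17268, of which 241 were removed by the input filter, 1771 by the local filter and 0 as clonal. Per the submitters' processing notes, the build is hg38 and the tools were FastQC, Trim Galore 0.6.10, Bowtie2, Picard, deepTools 3.5.5 and HOMER 4.11. The settings of the aligner and the duplicate removal are not given in the sources used here. The transposase inserts at its own preferred sites and cuts both strands, and whether tags were shifted for that is not given either, so a peak centre is known to within the width of the peak only.

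The deposited file has 6 columns, and its score column holds the value 1 in each of the 15256 lines. It therefore carries no height, fold enrichment or p-value for single peaks, although the header lists such columns. The order of the lines is not by position. Within each chromosome it follows the number in the peak identifier, with a Spearman correlation of at least 0.990 across peaks, and the list runs through the genome in order between 479 breaks, as a list sorted by a discrete quantity with ties in genome order does. The file does not name the quantity, so the place in the list is given only as the deposited order.

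Coordinates were counted from 1, and each peak of 146 bp was represented by its centre. Genes came from a RefSeq table of assembly GRCh38.p14, which is the same primary assembly as hg38. It gives the span of each gene and not its strand, its exons or its transcription start sites. The planned promoter results were therefore measured at either end of a gene span, within 1 kb, and are called gene-end peaks. With no strand, a gene-end peak may lie at the start or at the end of transcription. No genome sequence was used, so the planned tests of 24 motifs, the MYB element among them, and of the peak score by motif count were not run. The matching of random gene lists on promoter CpG content was replaced by matching on gene density. The planned restriction to the better-scoring peaks was replaced by the first 7628 lines of the list, a setting chosen after the constant score was seen.

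Comparisons used 15218 peaks on chromosomes 1 to 22 and X and 19970 protein-coding genes. The background for positions was 100 sets of random positions, as many as peaks on each chromosome, drawn in the 1 Mb bins that hold part of an annotated gene. Those bins stood in for the assembly gaps. Shares are given with 95% Wilson intervals. These intervals cover counting error only, since tags from a single amplified library are not independent molecules and peaks are not replicates. No p-value was computed, because the pulldown is a single library from a single condition.

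The 16 gene lists held 20 to 35 genes each, 407 different genes in all, and were fixed before the data were examined from general knowledge of the cell type. All 407 symbols were found in the table. A gene counted as occupied when at least 1 peak centre lay in its span extended by 10 kb on both sides. Each list was compared with 10000 random lists of the same size, matched gene by gene on 10 classes of gene length and 3 classes of the number of protein-coding genes within 500 kb. The place of a list is given as its percentile among these random lists, where a random list with the same count was counted in part as lower. A list above the 97.5th percentile is said to be above its matched lists, and chance alone would put 0.4 of 16 lists there. Expression is not part of these data, so the matching does not separate occupancy from gene activity. Clusters were chains of at least 3 peaks with no more than 12.5 kb between neighbouring centres.

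The rule for named genes was also fixed before the data were examined. It named MYB, the 10 highest-scoring peaks, the 10 protein-coding genes with most peaks, up to 4 members of each list with most peaks, the members without a peak in the lists of MLL-AF4 targets and haematopoietic transcription factors, and the 5 fullest clusters. One gene that the rule named is not reported here. With a constant score, ties were broken by alphabet for genes and by genome order for clusters, and the peak rule was applied to the deposited order, because its planned fallback on MYB motif matches needs sequence. That change was made after the data were seen. The genes named for their gene-end peaks, the members without a peak in other lists, and the regions around MYC and BCL2 were chosen after their values were seen. The comparison of gene ends that face a divergent transcript was also added after the data were seen.

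The scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated data, in 20 simulations over the 19970 genes. With peaks placed at random, 2.5% of the list tests came out above the 97.5th percentile. A list with peaks planted in 60% of its members was found in 100% of the simulations. Planted gene-end shares were recovered to within 0.0835 percentage points.

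Depth limits what can be said of absence: a region needed 10 tags to be listed, so a gene without a peak is one at which none was called at this depth. The depth of the input library is not given in the sources used here.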

Results

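The series profiled where tagged MYB sits on the genome of SEM cells, by pulldown of the HA epitope. MYB is a transcription factor of blood progenitors, and SEM is a pro-B leukaemia line that carries the MLL-AF4 fusion. One HA pulldown and 1 input library were made from cells in vehicle for 24 hours. The pulldown held 14948117 tags, of which 365696.5 fell in peaks as HOMER counts them. That was 2.45% of all tags (95% Wilson interval 2.44% to 2.45%), or 23.97 tags per peak on average against 1.074 expected per peak from the mean tag density. A peak needed 10 tags to be listed, so a gap of this kind follows from the calling threshold and is no measure of enrichment. The authors' list held 15256 peaks after comparison with the input. As there was a single pulldown, no value below has a replicate error, and all percentiles describe this list.

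Most MYB peaks lay away from gene ends, and the 53.6% that lay inside protein-coding genes (95% interval 52.8% to 54.4%) exceeded the 44.6% of random positions that did so (range over 100 sets, 43.7% to 45.5%). Peaks within 1 kb of an end of a protein-coding gene numbered 2065 of 15218, a share of 13.6% (13.03% to 14.1%). Random positions gave 2.74% (2.46% to 3.02%), so gene ends were over-represented 4.94-fold. Peaks more than 10 kb outside any protein-coding gene made up 30.7% (30.0% to 31.5%), against 47.3% of random positions (46.4% to 48.1%) and 34.1% of peaks moved by 10 to 50 kb (33.5% to 34.7%). The median distance from a peak to the nearest gene end was 21.7 kb, that of random positions was 52.3 kb and that of peaks moved by 10 to 50 kb was 24.99 kb. When each peak was moved by 10 to 50 kb to keep its neighbourhood, 4.08% of positions fell at gene ends and the excess was 3.33-fold. With these moved positions as background, the share inside genes but over 1 kb from an end turned from an excess of 1.11-fold to a deficit of 0.908-fold.

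Gene-end peaks were concentrated late in the deposited order. They were 8.08% of the first 1522 peaks (6.82% to 9.56%) and 17.5% of the last 1522 (15.7% to 19.5%), and the intervals did not overlap. Because the gene table lacks strand, the start of a gene was identified only where a divergent transcript is annotated, a noncoding RNA named for starting beside its partner gene. Of 518 such genes at least 5 kb long, 67 had a peak within 1 kb of the end that faces the divergent transcript, 12.9% (10.3% to 16.1%). At the opposite end 8 of the same genes had one, 1.54% (0.785% to 3.02%). Genes with a peak at the facing end included RB1, the retinoblastoma cell cycle inhibitor, NIPBL, the cohesin loader, and FOXP1, a transcription factor of B cell development.

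**Figure D1:**
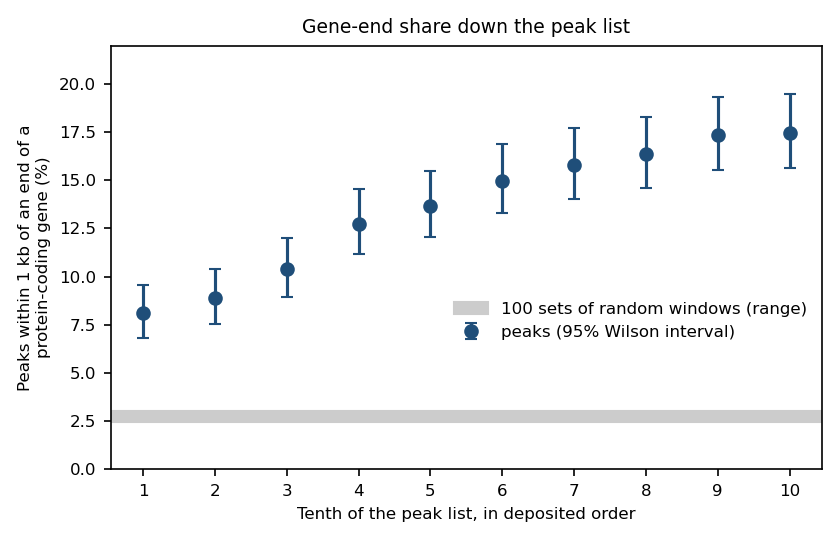
Share of peaks within 1 kb of either end of a protein-coding gene (y axis, %) in each of 10 consecutive parts of the peak list in deposited order (x axis); points are shares of about 1522 peaks with 95% Wilson intervals and the grey band is the range over 100 sets of random positions. The share runs from 8.08% at the head of the list to 17.5% at its tail, and every point lies above the random range of 2.46% to 3.02%.

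The 10 peaks that head the list on chromosomes 1 to 22 and X were mostly distal: 9 lay more than 10 kb from an end of a protein-coding gene and 6 lay inside one. The leading peak was in PAN3 at chromosome 13, 28268879 to 28269024 (hg38), a neighbour of FLT3, the receptor kinase gene. This part of the chromosome was dense in peaks, with 128 from 24 Mb to 34 Mb against a median of 49 per 10 Mb window. Copy number was not measured here, so neither this density nor the peak's place in the list was separated from extra copies of this part. Other leading peaks were in PITPNM2 (chromosome 12, 123132118 to 123132263), GSE1 (chromosome 16, 85571899 to 85572044), CDK6 (chromosome 7, 92639731 to 92639876), ELF1 (chromosome 13, 41004952 to 41005097) and LAT2 (chromosome 7, 74217691 to 74217836). CDK6 is a cell cycle kinase, ELF1 an ETS-family transcription factor and LAT2 an adaptor of lymphoid receptor signalling. The peak in LAT2 was the closest of these to a gene end, at 7.76 kb. Of the 4 leading peaks outside protein-coding genes, 1 lay 21.9 kb from DUSP1, a phosphatase of MAP kinases, at chromosome 5, 172793016 to 172793161. Another lay 42.4 kb from NUDT7 at chromosome 16, 77680008 to 77680153. The remaining pair lay in noncoding RNA genes, with PTPRC (CD45) 284 kb and ADGRB3 746 kb away as the nearest protein-coding ends.

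Peaks were found in or within 10 kb of 7075 of 19970 protein-coding genes, 35.4%, and within 1 kb of an end of 2157, 10.8%. At least 5 peaks were counted for 391 genes. RAD51B, a recombination repair gene, had 20, ZMIZ1, a coregulator of transcription, had 19, and MSI2, an RNA-binding protein of blood stem cells, had 18. GSE1, IQSEC1, TRAPPC9 and XYLT1 had 17 each, and ADARB2, GAS7 and SEPTIN9 had 15 each. These 10 genes were all long, from 219 kb to 863 kb. Only 3 of their 170 peaks lay within 1 kb of a gene end. Relative to length, ZMIZ1 carried 7.10 peaks per 100 kb and RAD51B 2.26. None of these peaks lay within 10 kb of another protein-coding gene.

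Genes of the B cell lineage carried MYB peaks more often than matched random genes. Of 34 B-lineage genes, 31 had a peak in or within 10 kb, 91.2% (77.0% to 97.0%), and matched random lists averaged 39.7%. None of the 10000 random lists reached that count. EBF1, an early B cell transcription factor, and ERG, an ETS factor of blood progenitors, had 7 peaks each, all inside the gene. BLK, a B cell tyrosine kinase, and CD9, a surface tetraspanin, had 6 each. Gene-end peaks were counted at 10 of the 34 genes, 29.4% (16.8% to 46.2%), against 10.9% in matched lists (percentile 99.9). They included both surrogate light chain genes of the pre-B receptor, VPREB1 with 1 gene-end peak and IGLL1 with 2. The VPREB1 peak lay within 1 kb of both ends of this 0.73 kb gene. The receptor chains CD79A and CD79B had 1 each, and POU2AF1, a B cell coactivator, had 3. The POU2AF1 peaks were all within 10 kb of BTG4 too, those of CD79A within 10 kb of RPS19, that of CD79B within 10 kb of SCN4A and those of IGLL1 within 10 kb of DRICH1. PAX5 and IKZF1, central regulators of B cell identity, had 1 peak each. CD24, IRF4 and IRF8 had none.

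Among 30 genes known as targets of MLL-AF4, 22 had a peak, 73.3% (55.6% to 85.8%), against 40.9% in matched lists (percentile 99.995). ARID1B, a chromatin remodelling subunit, had 14 peaks, RUNX1, a master factor of haematopoiesis, had 13, and CDK6 and JMJD1C, a histone demethylase-family gene, had 11 each. One of the JMJD1C peaks was also within 10 kb of REEP3. RUNX1 had 1 gene-end peak and the other 3 genes had none. Over the list, gene-end peaks were counted at 4 of 30 genes, 13.3% (5.31% to 29.7%), a value inside the range of matched lists (percentile 79.2). With a window of 2 kb the count rose to 8 of 30, which stood above matched lists (percentile 98.5). No peak was called in or within 10 kb of BCL2, CPEB2, FUT4, HOXA5, HOXA6, MYB, PBX3 or ZNF521. In the HOXA cluster, HOXA9 and HOXA10 each counted the same 2 peaks, and HOXA7 counted 1 of them. The matched lists were drawn without regard to such neighbours.

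Haematopoietic transcription factors were occupied at 24 of 33 genes, 72.7% (55.8% to 84.9%), against 42.3% in matched lists (percentile 99.975). After RUNX1 with 13 peaks came MEF2C, a factor of lymphoid progenitors, with 11, ETV6, an ETS-family repressor, with 9, and ERG with 7. Gene-end peaks were present at 8 of the 33 (24.2%, percentile 98.8), among them GFI1, KLF2 and BCL6 with 1 each. In the first 7628 lines that count was 3 of 33, inside the range of matched lists (percentile 89.96). No peak was called at GATA2, HHEX, IKZF2, IRF8, KLF6, MYB, PBX3, STAT5A or TAL1. The list shares members with others, and its 16 genes found in no other list gave 11 with a peak, 68.8%, still above matched lists (percentile 98.7). The 18 such MLL-AF4 targets gave 13, 72.2% (percentile 99.97), and the 30 such B-lineage genes 28, 93.3%. Expression was not matched and no pulldown from untagged cells was analysed here. Binding of MYB was therefore not separated from general signal at active genes in any of the lists.

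**Figure D2:**
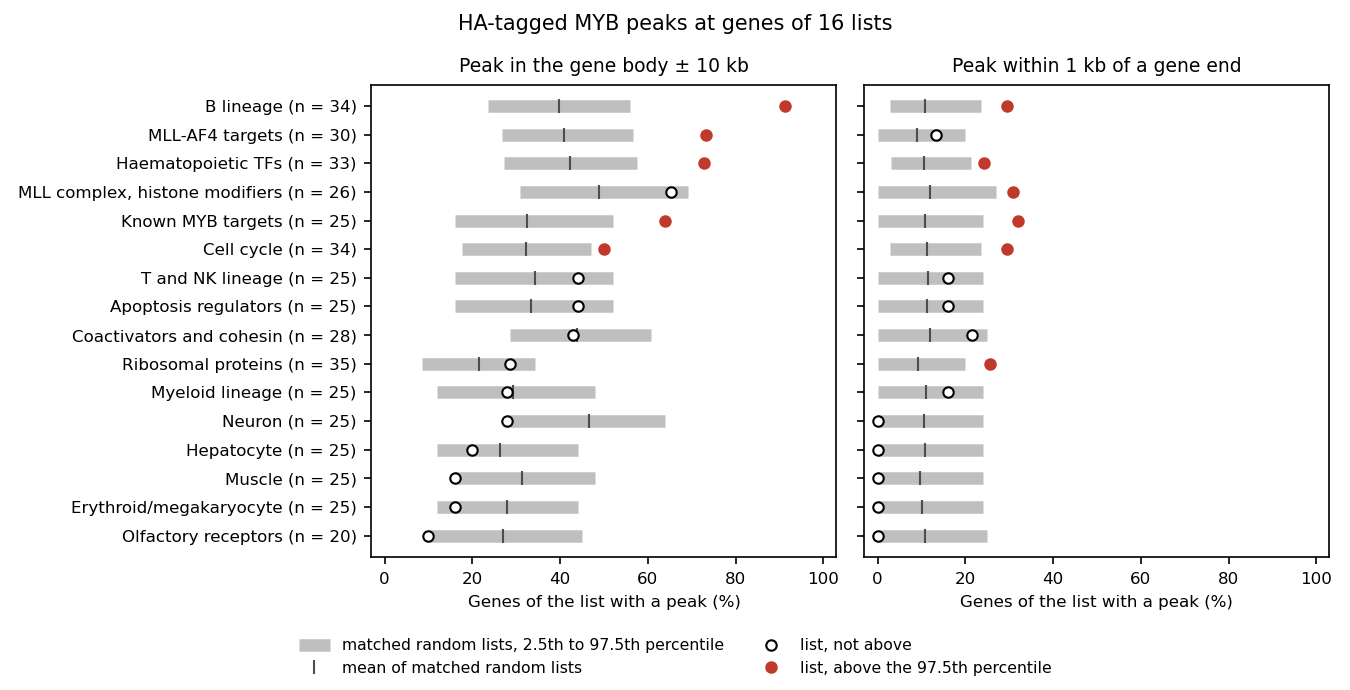
Share of the genes of each of 16 lists (y axis, with the number of genes) that carry a MYB peak (x axis, %), in the gene body extended by 10 kb (left) or within 1 kb of a gene end (right); circles are the lists, red where above their matched lists, grey bars the central 95% of 10000 matched random lists and ticks their means. B-lineage genes stand at 91.2% on the left, and 5 lists on the left and 6 on the right are above their matched lists.

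Of 25 genes described as MYB targets in the literature, 16 had a peak, 64.0% (44.5% to 79.8%), against 32.4% in matched lists (percentile 99.955). CDK6 led with 11 peaks, followed by IGF1R, a growth factor receptor, with 4, and the lymphoid transcription factors ETS1 and GATA3 with 3 each. Gene-end peaks were present at 8 of the 25, 32.0% (17.2% to 51.6%; percentile 99.8). They lay at MYC, GFI1, RAG2, MAT2A, MPO, ANPEP, BIRC3 and CXCR4, and MAT2A, which makes the methyl donor S-adenosylmethionine, had 2 of them, both within 10 kb of GGCX too. The 9 genes of this list found in no other gave 6 with a peak, 66.7% (percentile 98.9). Members without a peak included CCNB1, CCND1, CCNE1, ELANE, HSPA5 and PTGS2.

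Around MYB itself, which spans chromosome 6, 135181308 to 135219172, peaks were distal. The nearest was 52.6 kb from the gene, and 5 peaks lay in the interval between HBS1L and MYB, 52.6 kb to 93.9 kb from the MYB span. The highest-placed of these was at 135087975 to 135088120, on line 576 of the list. One peak lay 61.7 kb beyond the other end of the gene. MYC had 1 peak at a gene end, at chromosome 8, 127735407 to 127735552, and 9 within 500 kb, of which 4 were inside PVT1, the neighbouring noncoding RNA gene. BCL2, an apoptosis inhibitor, had none within 10 kb but 5 within 50 kb. Among those, 2 stood at lines 188 and 284 of the list and lay 24.6 kb and 23.04 kb from the gene, at chromosome 18, 63098638 to 63098783 and 63100237 to 63100382.

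**Figure D3:**
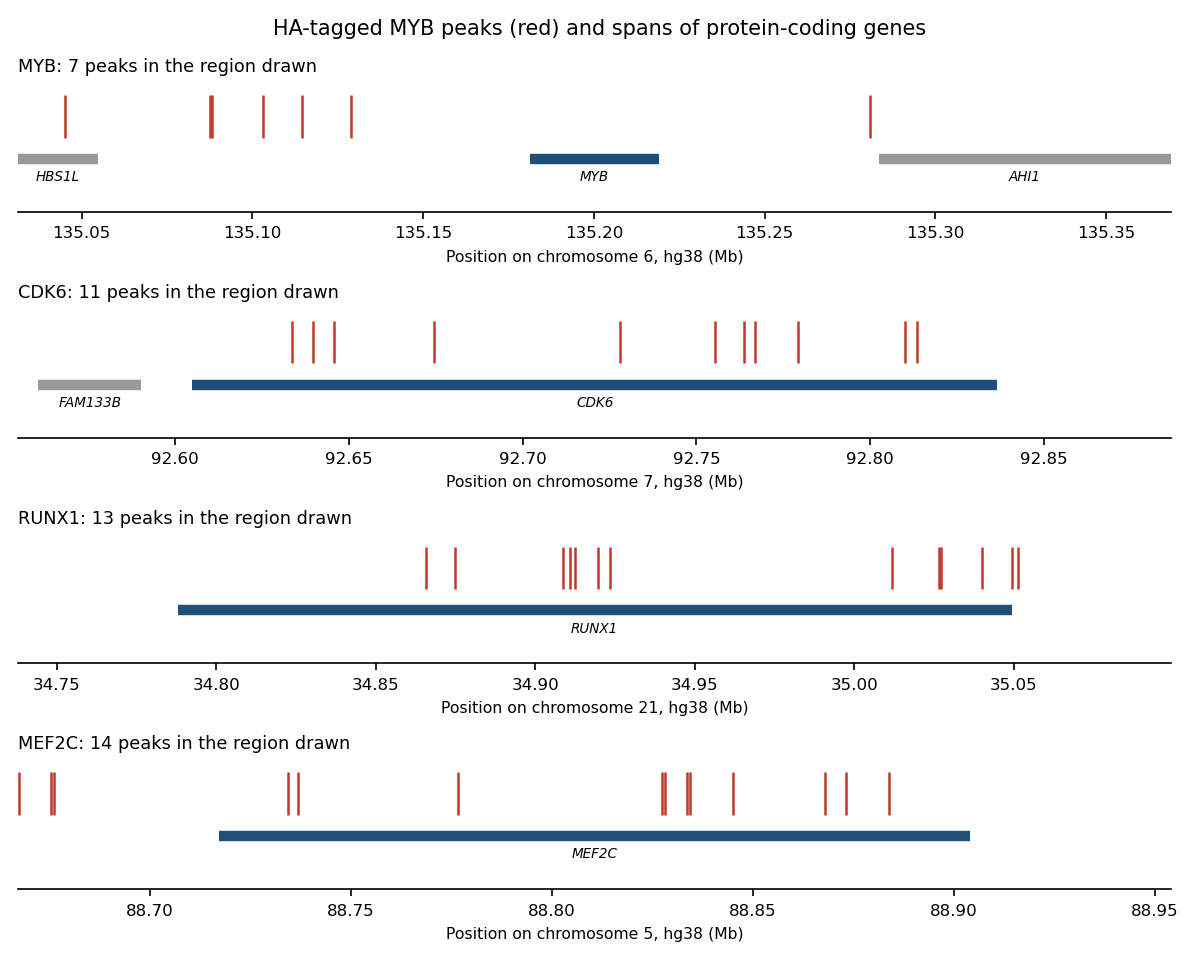
Positions of MYB peaks (red lines) along 4 regions in hg38 coordinates (x axis, Mb), with the span of the named gene in blue and of other protein-coding genes in grey; the MYB panel adds 150 kb on each side of the gene and the others 50 kb, and the y axis has no scale. No peak falls in MYB, where 7 peaks are drawn, whereas CDK6 and MEF2C each hold 11 peaks inside the gene and RUNX1 holds 12.

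Cell cycle genes had a peak at 17 of 34, 50% (34.1% to 65.9%), against 32.3% in matched lists (percentile 98.5). CDK6 had 11, the cyclin gene CCND3 had 7, and E2F2 and RB1 had 4 each, of which 3 at CCND3 were also within 10 kb of BYSL and 3 at RB1 within 10 kb of LPAR6. This list fell inside the range of matched lists under 4 other settings: in the first 7628 lines (percentile 82.6), with 50 kb extensions (97.1), with each peak given to its nearest gene end (91.3) and without matching (95.5). Gene-end peaks were present at 10 of the 34, 29.4% (16.8% to 46.2%; percentile 99.8), including CDK1, CDC20, AURKA, TOP2A, WEE1, PCNA, MCM4 and E2F1 with 1 each. In the first 7628 lines that count was 3 of 34, inside the range of matched lists (percentile 86.9).

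Ribosomal protein genes had gene-end peaks at 9 of 35, 25.7% (14.2% to 42.1%; percentile 99.8), but peaks within 10 kb at 10 of 35, 28.6%, inside the range of matched lists (percentile 84.2). In the first 7628 lines the gene-end count was 4 of 35, also inside that range (percentile 96.7). RPS19 had 3 peaks and RPL15 had 2, and RPL18 and RPL19 had 1 each, all of them within 10 kb of another protein-coding gene. Genes of the MLL complexes and histone modifiers had gene-end peaks at 8 of 26, 30.8% (16.5% to 49.99%; percentile 99.4), and peaks within 10 kb at 17 of 26, 65.4% (percentile 95.8). With 50 kb extensions, with nearest gene ends and without matching, that last share stood above matched lists (percentiles 98.2, 98.2 and 99.9). AFF1, DOT1L and MLLT10, all tied to MLL fusions, had 4 each, and KAT7, a histone acetyltransferase gene, had 3. All peaks of DOT1L and KAT7, 2 of MLLT10 and 1 of AFF1 were also within 10 kb of a neighbouring gene. AFF1 takes part in the translocation of this line. Coactivator and cohesin genes lay inside the range of matched lists for both measures. They had a peak at 12 of 28, 42.9% (percentile 46.4), and had gene-end peaks at 6 of 28, 21.4% (percentile 92.5). CDK9, the elongation kinase, had 4 peaks that all lay within 10 kb of SH2D3C or FPGS, MED14 and WAPL had 2 each and CCNT1 had 1. Apoptosis regulators had a peak at 11 of 25, 44.0% (percentile 86.9), with 6 at BID, 5 at BCL2L1 and 4 each at BIK and CASP8, of which 2 each at BID, BIK and CASP8 were shared with a neighbouring gene. Gene-end peaks were present at 4 of these 25 genes, 16% (percentile 77.1). With 50 kb extensions this list rose above matched lists, at 21 of 25 (percentile 99.8), as it did with each peak given to its nearest gene end (percentile 99.3).

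Lists for other lineages were not above matched lists. T and NK cell genes had a peak at 11 of 25, 44.0% (26.7% to 62.9%; percentile 85.3), with 6 at ZAP70, the T cell receptor kinase, 3 at GATA3 and 2 each at CD28 and LCK. Of the ZAP70 peaks, 2 were also within 10 kb of TMEM131. Myeloid genes had a peak at 7 of 25, 28.0% (percentile 45.4), with 4 at CSF1R and 1 at ANPEP. The peaks at CD68 and CSF3R, 2 each, were all shared with neighbouring genes, as was 1 of those at CSF1R. Erythroid and megakaryocyte genes had one at 4 of 25, 16% (percentile 8.79), with 2 at GP9 and 1 each at GATA1 and NFE2 among them. For hepatocyte genes the count was 5 of 25, 20% (percentile 23.995), with 1 peak each at AMBP, APOA2, CYP3A4 and F9 among them. Muscle genes gave 4 of 25, 16% (percentile 4.12), with 1 peak each at MB, MYH6, MYH7 and NEB, MYH6 and MYH7 sharing theirs. Neuronal genes gave 7 of 25, 28.0%, against 46.7% in matched lists (percentile 2.60), with 4 peaks in the 2304 kb of CNTNAP2, 3 each in MAP2 and RBFOX3 and 2 in SYT1. Olfactory receptor genes gave 2 of 20, 10.0% (percentile 3.48), OR2B2 and OR4D1 with 1 each. With 50 kb extensions the neuronal and the olfactory receptor genes stood below the central 95% of matched lists (percentiles 1.31 and 0.250). The same held with nearest gene ends for the muscle genes (1.45) and without matching for the olfactory receptor genes (0.685). Other shares were also below matched lists by percentile, under 2.5, although they equalled the lower bound of that central 95%. These were the hepatocyte genes with nearest gene ends (2.25), the erythroid and muscle genes without matching (2.17 and 1.89), and the neuronal genes without shared members (2.29). None of the erythroid, hepatocyte, muscle, neuronal or olfactory receptor genes had a gene-end peak. A count of 0 allows a share of up to 12% for the lists of 25 and 15.0% for the list of 20. Matched lists averaged 9.69% to 10.8%, and their central 95% reached down to 0%. No single list could therefore fall under that range, and a list taken alone neither shows nor excludes a deficit. All of these lists lay on the same side, however, with percentiles from 2.80 to 5.055. That goes with fewer gene-end peaks over the lists together, for which no joint test was run. Within 2 kb the hepatocyte genes, still at 0, stood below the central 95% of matched lists (percentile 1.25). The erythroid and olfactory receptor genes, also at 0, were below by percentile too, at 1.37 and 2.37, although the central 95% of their matched lists reached down to 0%.

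MYB peaks were grouped along the genome. Chained by distance, 724 clusters of at least 3 peaks held 2542 peaks, 16.7% of all (16.1% to 17.3%). Random placement gave 70.2 clusters on average (51 to 87), a 10.3-fold difference. Moving each peak by 10 to 50 kb gave 467 (422 to 506), which left a 1.55-fold difference. The fullest clusters held 9 peaks each, 1 at FBLN7, an adhesion protein gene (chromosome 2, 112155618 to 112188242), and 1 in LIPC, the hepatic lipase gene (chromosome 15, 58433961 to 58483707). Clusters of 8 peaks lay in ADGRD1 (chromosome 12, 131023996 to 131061450), in GAS7 (chromosome 17, 10115340 to 10157147) and at chromosome 8, 60909420 to 60951223, 13.7 kb from CLVS1.

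Peak density differed between chromosomes. Chromosome 19 had 9.51 peaks per Mb of annotated span and chromosome 17 had 8.59, whereas chromosome X had 1.88. Per protein-coding gene the order changed: chromosome 13 had 1.47 peaks per gene, chromosome 8 had 1.42, chromosome 19 had 0.384 and chromosome X 0.346. With 1 library, a difference between chromosomes cannot be separated from their copy number in this line.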

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

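The contig count given here was examined only after the peaks had been seen, and no explanation was tested. A signal appeared in sequences that the comparisons leave out: 37 peaks lay on 21 unplaced, unlocalised or alternate contigs. Among the first 20 lines of the list, 4 were such peaks, on 2 unplaced contigs. No biological explanation was tested for them.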

How the results depend on the processing

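The settings that use the first 7628 lines, the remaining lines, the moved peaks, the unshared list members or chromosomes 1 to 22 and X (15218 of 15256 peaks), or leave out tRNA and histone genes were chosen after seeing the data, and the other settings before. The gene-end share of 13.6% became 18.1% within 2 kb, 20.1% with all annotated genes, 10.8% in the first 7628 lines and 16.4% in the remaining lines. It stayed within its interval when any base of the peak counted (14.003%) and without the 118 peaks at tRNA or histone genes (13.3%). Its excess stayed within 1.5 times, at 4.94-fold over random positions and 3.33-fold over moved peaks. The 724 clusters became 271 when chained within 5 kb, against 12.6 by random placement, and 226 in the first 7628 lines, against 9.79, and their excess fell from 10.3-fold to 1.55-fold when moved peaks were the background. Lists above matched lists numbered 5 for peaks within 10 kb and 4 to 6 under the other settings, where B-lineage genes, MLL-AF4 targets, haematopoietic factors and known MYB targets were above in each. For gene-end peaks there were 6, with 7 within 2 kb and 3 in the first 7628 lines. Of 112 shares of single lists under other settings, 24 moved out of their interval, and no list that stood above its matched lists fell under their mean. The 16 shares without matching could not move, because that setting changes only the random lists. Nor could the unshared-member shares of lists that share no gene, so the 112 overstate how many shares were put to a test. The settings that need a peak score or a sequence (better-scoring peaks, motif windows, consensus and backgrounds) were not run. The cause of these shifts was not tested beyond the construction of each setting. No paired analysis was possible because the pulldown is a single library and no peak list of the input was analysed here. Depth limits absence: a site with under 10 tags was not listed.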

Other observations

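All values and groups in this part were chosen after the peaks had been seen. The tests of tRNA gene copies and of moved positions were written before their results, and the tests on chromosome 13 and on ribosomal protein genes after.

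Genes for tRNAs, snRNAs and histones carried MYB peaks more often than moved positions. A peak centre lay within 500 bp of the middle of 93 of 443 tRNA genes, 21.0% (17.5% to 25.0%), and of 21 of 154 snRNA genes, the spliceosomal RNA genes and their relatives, 13.6% (9.10% to 19.9%). Clustered H1, H2A, H2B, H3 and H4 genes had one at 25 of 69, 36.2% (25.9% to 48.0%), with H1-2, H1-3, H2BC9 and H4C8 among them. Positions moved by 5 to 50 kb gave 1.57%, 0.610% and 5.74%. Genes for snoRNAs had a peak at 9 of 1196, 0.753%, and moved positions gave 0.700%. Genes for miRNAs had one at 36 of 1911, 1.88% (1.36% to 2.60%), and moved positions gave 0.884% (0.419% to 1.41% over 100 sets). Of the antigen receptor loci, the T cell receptor alpha and delta locus on chromosome 14 held 23 peaks over 930 kb, more than 98.3% of random spans of that length on the chromosome. The immunoglobulin lambda locus held 19 over 897 kb (percentile 94.1), the heavy chain locus 4, the kappa locus 5, the T cell receptor gamma locus 1 and the beta locus 0.

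The peaks at tRNA and histone genes invite a technical reading. Reads shared between copies of the same family are argued against as the whole cause for tRNA genes, because those of single-copy families had a peak at 16.3% (11.9% to 22.1%). Those of families with 2 or more copies had one at 24.9% (19.9% to 30.7%), and a part from such reads stays open. Without sequence, the likeness between families was not measured, so reads shared across families stay open too. A dense neighbourhood is argued against too, since moved positions reached at most 3.61% over 100 sets for tRNA genes and 11.6% for histone genes, below the lower bounds of 17.5% and 25.9% at the genes themselves. General signal at heavily transcribed open genes stays open: ribosomal protein genes, which are transcribed heavily, were at the 99.8th percentile of matched lists for gene-end peaks, as this reading needs, though at 96.7 in the first 7628 lines. Binding of MYB at these genes stays open as well and may hold for some of them, and a pulldown from untagged cells, not analysed here, would separate the readings.

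Chromosome 13 lost more candidates to the authors' filters than other chromosomes: of the first 803 peak numbers, 306 were absent from the list, 38.1%, against 5.59% to 16.3% elsewhere. At least 65 of these were removed by the local filter, because the input filter removed 241 in all and the clonal filter 0. Weak candidates alone are argued against if low numbers mark strong candidates, which the file does not state: 35.0% of the absent numbers were in the lower 50% of the numbers, where no other chromosome exceeded 26.7%. Extra copies of part of the chromosome stay open, and peak density did not decide it: the fullest 10 Mb window, from 24 Mb to 34 Mb, held 2.29 peaks per protein-coding gene, more than the fullest windows of 95.5% of the other 22 chromosomes, but that of chromosome 8, 132000001 to 142000000, held 4.48 while chromosome 8 lost 16.3% of its numbers. A stretch rich in MYB sites would give a high density too, and no biological explanation was tested.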
